A study of Homo sapiens and Mus musculus and Caenorhabditis elegans with 95 samples.

How the data were processed

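The series holds 95 samples in 48 groups. CapTag-seq, which releases the capped 5′ end of bulk mRNA as a short tag and sorts the tags by length, was run on 34 libraries and on 5 mRNA standards. CLAM-Cap-seq, which measures Cap2 methylation at single transcription start nucleotides (TSN), was run on 10 libraries. Start sites were also sequenced after actinomycin D (16 libraries at 0, 2, 8 and 16 h of 5 µg/ml), in polysome fractions 1 to 5 (20 libraries) and in untreated MCF-7 and mouse embryonic stem cells (2 libraries). RNA-seq covered 8 libraries. The labels place 2 replicates in each CapTag-seq source, 4 in CLAM-Cap-seq of wild type (WT) HEK293T and 2 in the other CLAM-Cap-seq sources, and 4 in each RNA-seq group. No label says that replicates were separate cultures or animals, so every p-value measures the spread between these samples.

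The deposited CapTag-seq files give tag counts per tag length and, per the file headers, Cap1 and Cap2 tag counts per dinucleotide. They also give a percent, which the authors computed as 3-nt tags (Cap2) over 2-nt plus 3-nt tags (Cap1 plus Cap2). Recomputed from the counts, it differed from the deposited percent by at most 2.4e-09. The deposited CLAM-Cap-seq tables give the Cap2 level of each TSN isoform and replicate as a percent, without the reads behind it. The deposited tables of TSN contribution give each start site's fraction of the strongest site of its gene. The deposited half-lives are in hours and the deposited mean ribosome loads in ribosomes per mRNA, both other units than counts, made by the authors from the actinomycin D course and from the polysome fractions by steps that are not stated. RNA-seq was deposited as unscaled counts per Ensembl gene with 92 spike-in controls (ERCC), and the authors' own comparison as log2 fold changes with an unadjusted p-value per gene from a likelihood ratio test. The submitters' processing notes name Bowtie 1.2.3, bedtools 2.28.0 and the builds hg38, mm10 and dm6, without saying which step each served. No genome sequence was at hand, so nothing below depends on the bases at a start site. Gene symbols were found for 19725 of 19840 Ensembl identifiers.

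Depth is known for CapTag-seq, with 4267413 to 44098078 tags per library, and for RNA-seq, with 18156936 to 29312651 gene counts. It is unknown for the percent, half-life and ribosome load tables, so no interval is given there. Wilson intervals at 95% cover counting error alone, since reads amplified by PCR without molecular identifiers are not independent molecules. In all 17 CapTag-seq groups with 2 libraries, the replicates differed by more than counting error.

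Bulk Cap2 levels were compared with two-sided exact permutation tests for 2 groups, and with permutation of the F ratio for several sources. The F ratio was enumerated over all 105 regroupings of the cell lines and all 15 of the whole animals, and over 100000 resamples for the organs. Nucleotides were compared within each of the 10 WT mammalian sources by an exact sign-flip permutation test over sources, adjusted by Benjamini-Hochberg over 12 nucleotide pairs. The first and second transcribed nucleotides are written Nm, as in AmG for a first A and a second G.

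Cap2 levels, log2 half-lives and log2 mean ribosome loads per isoform were compared with limma 3.58.1, with the spread modelled as a trend on the mean. A test on read counts had been planned for CLAM-Cap-seq and was replaced by limma on the percent, because the tables hold percents and no counts. RNA-seq was tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr, prior count of 1 for log CPM). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. On simulated data with these group sizes, edgeR recovered 86 of 100 genes changed by 0.5 on the log2 scale and 98 of 99 changed by 1, with 12 calls among the unchanged of 13397 genes. In the same kind of test, limma recovered 106 of 200 isoforms changed by 10 percentage points of Cap2. For half-lives it recovered 0 of 200 changed by 1 on the log2 scale and 142 of 200 changed by 2. For ribosome load it recovered 180 of 200 changed by 0.5. The edgeR simulation gave every gene the same dispersion and changed few genes, so its rates may not hold for the real comparison.

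Relations across isoforms or genes are Spearman's rho, computed in every pairing of a Cap2 replicate with a replicate of the other measure and given as the mean, with the SD over pairings. Isoforms and genes are not independent replicates, so no p-value is attached. Cap2 levels of gene lists are medians over genes of the mean over a gene's isoforms. They were set against 10000 random lists of the same size, matched in 10 bins of expression in HEK293T and unmatched in MCF-7 and mESC. Lists beyond the percentiles 2.5 and 97.5 were placed outside them. Lists with fewer than 5 measured genes were left out. Gene lists in RNA-seq were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over 19 lists. The lists were interferon-stimulated and RIG-I signalling genes, cap synthesis and decapping, cytosolic ribosomal proteins, translation factors with TOP mRNAs (a pyrimidine tract at the start), oxidative phosphorylation, mitochondrial ribosomal proteins, proteasome, glycolysis, immediate-early and other short-lived mRNAs, C2H2 zinc finger genes named ZNF, cell cycle, integrated stress and unfolded protein response, p53 targets, cholesterol synthesis, heat shock and chaperones, hypoxia, neuronal markers, epithelial and renal markers, and mesenchymal and matrix markers.

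The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. In RNA-seq the rule names CMTR2, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, and the 4 most changed members past the threshold of each list. For Cap2 it names the 8 highest and 8 lowest isoforms among those with coverage above the median and the 2 most covered members of each list. For differences between isoforms it names the 5 largest each way among those past the threshold. The tables used here hold no coverage. Genes above the median of WT RNA-seq expression (a mean log2 CPM above 5.33) stood in for it, and the isoform with the highest TSN contribution stood in for the most covered isoform. Genes and isoforms named outside the rule are marked as chosen after their values were seen. Genes were ordered along the chromosomes for 13263 of 13473 genes tested.

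The alternatives were DESeq2 1.42.0 size factors, library size alone, other count filters, glmTreat against a fold of 1.5, the DESeq2 Wald test, the logit of the Cap2 level, linear in place of log2 values, centred replicates, 1 isoform per gene, limits on half-life, expression filters, unweighted or equally weighted dinucleotides, the tables deposited under the assay's first name, a block on replicate number, and leaving out each library in turn. Scaling to the ERCC counts, limma without a trend, genes above the median expression in place of a coverage minimum, and the partial correlation given mean half-life were added after the data had been seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. First versions of the dinucleotide tables, which later series-level tables replaced, were left out.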

Results

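The ribose of the first transcribed nucleotides of an mRNA carries methyl groups next to the cap. Methylation of the first nucleotide alone gives Cap1, and CMTR2 adds the methyl group on the second nucleotide that makes Cap2. Cap2 was measured in bulk mRNA by CapTag-seq and at single transcription start nucleotides (TSN) by CLAM-Cap-seq. The sources were HEK293T cells (a human embryonic kidney line) with and without CMTR2, A549 and MCF-7 cells (human lung and breast cancer lines), mouse embryonic stem cells (mESC), 6 mouse organs, adult worms, adult flies and zebrafish embryos 48 h old. Half-lives after actinomycin D, which stops transcription, ribosome loads from polysome fractions, and RNA-seq compared knockout (KO) with wild type (WT) HEK293T cells. CapTag-seq libraries held 4267413 to 44098078 tags and RNA-seq libraries 18156936 to 29312651 gene counts. The depth behind the Cap2 percentages of single isoforms, the half-lives and the ribosome loads is unknown. Replicates are not stated to be separate cultures or animals.

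CMTR2 mRNA itself was present in every RNA-seq library. CMTR2 (ENSG00000180917.17, chromosome 16) stood at 18.5, 17.7, 17.3 and 16.2 CPM (counts scaled to library size and TMM factor) in the 4 WT libraries and at 22.4, 20.9, 19.5 and 20.2 in the 4 KO libraries. Its level rose by 0.26 on the log2 scale (edgeR, adjusted p = 0.00123). Its amount is thus no check on the KO label, for which the Cap2 level of the KO cells stands below.

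Bulk mRNA of WT HEK293T cells carried Cap2 on 40.8% ± 2.18 of its caps (SD, n = 2), and mRNA of CMTR2 KO cells on 0.689% ± 0.0815 (n = 2). The level fell at all 16 dinucleotides. In these 2 KO libraries it was lowest at GmU, with 0.411%, and highest at CmG, which read 12.5% against 26.5% in WT. CmA followed with 3.63% and UmC with 2.27%. The KO had been planned as the background of the Cap2 level. Whether these KO readings are Cap2 or background was not tested. The difference of -40.1 percentage points was many times the spread between libraries, and its exact permutation p of 0.333 is the smallest that 2 libraries against 2 can give. Without decapping, cap-derived tags made up 1.41% ± 0.0881 of all tags, against 53.8% ± 7.33 with decapping (n = 2 each), which is the background of the assay. Among those few tags, 16.7% ± 4.38 had the length of a Cap2 tag.

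Mixtures of mRNA from KO cells and from cells overexpressing CMTR2 served as standards, with 1 library each. Standard 1, KO mRNA alone, gave 0.678% Cap2 (Wilson 95% interval 0.671 to 0.684). There CmG had 3.92%, less than in the KO libraries above, and UmC was highest with 4.54%. Standard 5, overexpression mRNA alone, gave 67.3% (67.26 to 67.33). Standards 2, 3 and 4 held 33.33, 50 and 66.67% of the overexpression mRNA per the file headers, and gave 25.2, 36.8 and 49.2%. These values lay 2.34, 2.83 and 4.09 points above the straight line between the ends, beyond their counting intervals. The line takes both mRNAs to yield cap tags alike. Cap tags made up 18.2% of all tags in standard 1 and 21.5% in standard 5, and 19.0, 17.6 and 18.2% in standards 2, 3 and 4. Whether unequal yield accounts for the distance was not tested. The mixing ratios in the labels read the other way round for standards 2 and 4. The measured order of the levels follows the file headers.

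The cell lines and organs differed widely in bulk Cap2. MCF-7 cells had 56.4% ± 0.294 and A549 cells 54.5% ± 0.0230, HEK293T cells 40.8% ± 2.18 and mESC 24.9% ± 0.0587 (SD, n = 2 each). Among the mouse organs the level was lowest in brain, with 7.89% ± 0.00207, followed by liver with 14.1% ± 0.0810 and kidney with 16.8% ± 0.103. It was higher in lung, with 24.4% ± 0.0993, heart, with 25.4% ± 0.121, and spleen, with 30.2% ± 0.199. The organs spanned 22.3 percentage points. Worms had 0.881% ± 0.0931, while zebrafish embryos had 12.2% ± 0.0689 and flies 12.4% ± 0.000503. In worms, 85.6% of the cap tags started with Gm, and their low level is the plain value over that mix. Worm mRNAs starting with Cm and Um, 1.01% and 0.312% of the cap tags, had 22.4% ± 2.29 and 16.7% ± 1.56, and CmG 78.8% ± 0.809. In CMTR2 KO HEK293T cells, Cm, Um and CmG read 1.09, 1.23 and 12.5%. How much of the worm values is background was not tested. The lines differed with F = 351 (exact permutation p = 0.00952, the smallest of 105 regroupings). The organs differed with F = 10164 (permutation p = 0.00011), and for the animals the exact permutation p of 0.0667 is the smallest of 15 regroupings. Each organ, line and animal has 2 libraries, so single pairs were not tested. Brain levels weighted by the nucleotide mix of spleen gave 12.5%, and HEK293T levels at the mix of MCF-7 gave 41.6%.

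**Figure D1:**
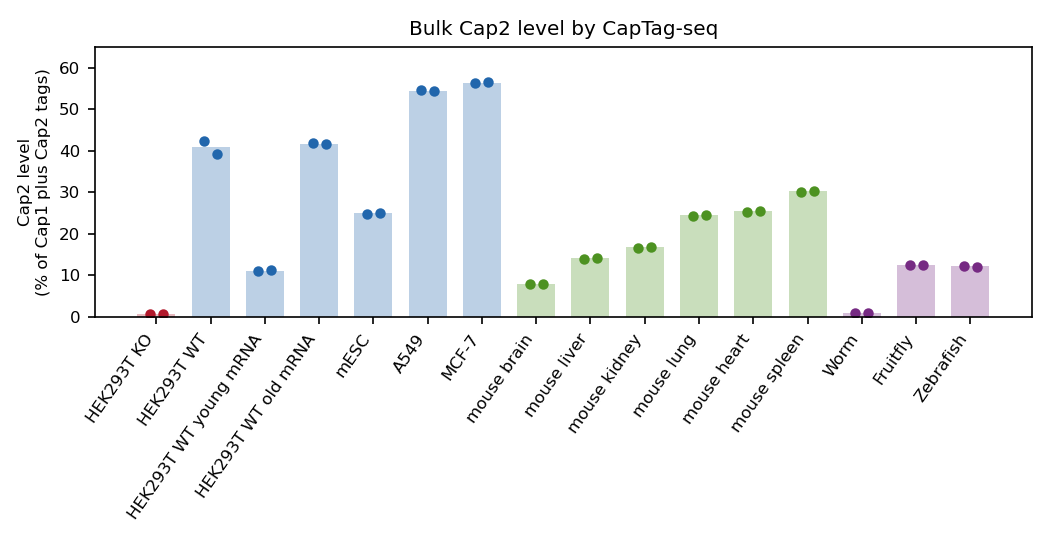
Bulk Cap2 level from CapTag-seq (vertical axis, percent of Cap1 plus Cap2 tags) in 16 sources, with bars for the mean of 2 libraries and points for the libraries. The bars run from 0.689% in CMTR2 KO cells and 0.881% in worms to 56.4% in MCF-7 cells.

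The nucleotides next to the cap went with different Cap2 levels. Across the 10 WT mammalian sources, mRNAs starting with Am had 38.7% Cap2 on average and those starting with Gm 18.8%, a mean difference of 19.96 percentage points ± 8.56 (SD over sources), higher in 10 of 10 sources. Am also exceeded Um, by 11.8 points ± 10.7 in 9 of 10 sources. Gm was lower than Um in all but 1 of the 10 sources, by -8.15 points ± 7.11. At the second nucleotide, Am was below Cm (-9.85 points ± 10.7, above it in 1 of 10 sources) and Gm below Um (-7.24 points ± 4.09, above it in 0 of 10). These 5 of 12 nucleotide pairs passed the threshold in exact sign-flip permutation tests, with adjusted p of 0.0117 for each, except second Am against Cm with 0.0234. In the 4 cell lines alone and in the 6 organs alone 0 pairs passed, which tells nothing of either, since so few sources leave adjusted p above the threshold even for pairs with 1 sign in all of them.

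Young and old mRNA were separated by a pulse of bromouridine (200 µM for 3 h) and a chase with uridine of 0 h (young) or 8 h (old) in WT HEK293T cells, to compare their Cap2 levels. Young mRNA carried 11.1% ± 0.0309 Cap2 and old mRNA 41.7% ± 0.310 (SD, n = 2 each), a ratio of 3.75. All 16 dinucleotides had more Cap2 in old mRNA, by a factor of 2.32 at UmC up to 5.50 at GmG. AmG went from 12.3 to 52.4% and AmU from 19.96 to 58.5%. Young levels weighted by the nucleotide mix of old mRNA gave 12.0015%. The mix of transcripts was not adjusted for. A larger share of long-lived mRNAs after the chase therefore cannot be told apart from a gain of Cap2 with age. The difference of 30.6 points far exceeded the spread between libraries, and its exact permutation p of 0.333 is the smallest that 2 against 2 can give.

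At single start sites, Cap2 ran from nothing to nearly all molecules. In WT HEK293T cells, 12776 isoforms of 3913 genes had a mean level of 23.2% ± 0.158 and a median of 14.9% ± 0.135 (SD over 4 replicates). The highest levels in well expressed genes belonged to IMMT, which shapes the cristae of mitochondria, with 95.7% ± 1.53 at position 86195462 of chromosome 2 (hg38), and to ATP5F1A, a subunit of ATP synthase, with 95.5% ± 0.457 at position 46098295 of chromosome 18. They were followed by MDH2, an enzyme of the citric acid cycle, with 95.1% ± 1.05. The antigen-presenting HLA-A and HLA-C had 94.8% ± 0.741 and 94.5% ± 1.103, COX5B 93.6% ± 1.15, RPL19 93.5% ± 1.18 and ACO2, also of the citric acid cycle, 93.3% ± 3.72. At the other end, isoforms of the chaperone genes HSPA4, STIP1, CCT6A and HSPH1, of RIF1 and UBAP2L, and 2 isoforms of LBR, a receptor of the nuclear envelope, were listed at 0 in all 4 replicates. They were among 125 isoforms listed at 0 in every replicate. Ties were broken by gene expression, so these names do not show which kinds of genes have the least Cap2. How many reads stand behind a 0 is not known.

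In CMTR2 KO cells, Cap2 was nearly gone from single isoforms as well. Over 16102 isoforms the mean was 0.359% ± 0.00894 (n = 2) and the median 0. The ATP5F1A isoform at 46098295 went from 95.5 to 0.231%, HLA-C from 94.5 to 0, HLA-A from 94.8 to 0.561%, COX5B from 93.6 to 0.407% and RPL19, a ribosomal protein, from 93.5 to 0.574%. Of 12523 isoforms tested with limma, 10601 fell, 7 rose and 1915 did not pass, with a median difference of -14.7 percentage points. The rises past the threshold included another ATP5F1A isoform 9 nt away at 46098286 (15.6 to 27.4%, adjusted p = 0.00208), RAVER1 (17.0 to 24.1%), PSMB1 (2.88 to 7.75%), HACD3 (0.953 to 3.25%) and SEPHS2 (0.765 to 2.81%). In the KO, 55 isoforms lay above 5% and 7 above 20%, looked up after their values were seen. The highest was ATP6V1D, a subunit of the vacuolar proton pump, with 66.3% in the KO and 75.3% ± 2.02 in WT. NKRF had 40.1%, DNAJC8 35.0% and AP2S1 24.5%, the last against 75.8% in WT. Whether such KO readings, the rises included, are Cap2 or background was not tested. WT levels at these sites may hold the same background. The count of rises was 13 without KO replicate 1.

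Start sites of the same gene often differed in Cap2. Among 2631 genes with at least 2 isoforms, the range within a gene had a median of 27.4 percentage points, and 1226 genes spanned more than 30. The median SD between replicates was 1.99 points. Start sites 1 nt apart differed by a median of 13.3 points over 1139 pairs, more than 30 points in 268 of them, and random pairs by 17.8. Differences between genes accounted for 48.1% of the variance between isoforms. Part of such a share arises by chance with so many genes, and how much was not computed. Among the widest ranges, looked up after the values were seen, were ACO2, with 93.3% ± 3.72 and 1.18% ± 0.592 at sites 8 nt apart, and OAZ1, the antizyme of ornithine decarboxylase, with 92.6% ± 0.311 and 2.15% ± 0.243 at sites 5 nt apart. YWHAE, a 14-3-3 protein, had 92.4% ± 0.324 and 0.555% ± 0.147 at sites 11 nt apart. Sites typed as major in the files had a median of 18.7% (3399 isoforms) and the others 13.6% (9377 isoforms).

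MCF-7 cells had more Cap2 than HEK293T cells at most shared start sites. Their 10630 isoforms had a mean of 38.6% ± 0.112 (n = 2), and mESC with 12773 isoforms a mean of 17.9% ± 0.00133 (n = 2). Of 7187 sites measured in both human lines, 5932 were higher in MCF-7, 17 were lower and 1238 did not pass (limma), with a median difference of 11.01 points. ATIC, an enzyme of purine synthesis, went from 3.23% in HEK293T to 52.3% in MCF-7. STMP1 went from 28.5 to 73.7%, NDUFA11 of respiratory complex I from 32.1 to 77.3%, NOP58 of the nucleolar methylation complex from 22.3 to 65.6% and CAP1 from 18.3 to 60.8%. Lower in MCF-7 were TMEM258 (37.8 to 21.2%), PRPF3 (34.1 to 22.2%), EMC2 (47.5 to 36.5%), the splicing factor SRSF1 (55.4 to 45.5%) and RPL10 (31.6 to 21.7%). Adjusted p-values of these named sites lay between 1.07e-05 and 0.00328. Across sites the levels of both lines ranked alike, with a mean rho of 0.964 over 8 pairings of replicates. Across 2462 genes matched by symbol, HEK293T and mESC had a mean rho of 0.438.

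Gene groups differed in Cap2 beyond lists of equal expression. Against a median of 17.1% over all genes of WT HEK293T, 13 glycolysis genes had a median of 52.2% ± 0.265 (SD over 4 replicates), with ENO1, the enolase, at 67.3% ± 0.394 and GAPDH at 51.6% ± 1.06. Ribosomal proteins (75 genes) had 42.3% ± 0.956, with RPL8 at 61.3% ± 0.402 and RPS6 at 45.3% ± 2.16. Translation factors with TOP mRNAs (21 genes) had 38.9% ± 1.18, with the elongation factor EEF2 at 72.8% ± 0.299 and RACK1 at 46.4% ± 1.07. Oxidative phosphorylation (60 genes) had 37.4% ± 0.808, with ATP5F1B at 60.2% ± 0.627 and ATP5F1A at 58.5% ± 0.637. Proteasome subunits (30 genes) had 30.5% ± 0.417, with PSMD1 at 29.4% ± 0.669 and PSMA4 at 46.0% ± 0.633, and 5 neuronal markers 45.4% ± 1.86, with UCHL1, a deubiquitinating enzyme, at 81.9% ± 4.17 and NEFM at 10.1% ± 3.75. All of these lay above the central 95% of 10000 random lists.

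Lists of short-lived and regulatory mRNAs had low median Cap2. Immediate-early and other short-lived mRNAs (18 genes) had a median of 4.16% ± 0.931, with the transcription factor JUN at 8.36% ± 1.58 and the survival factor MCL1 at 34.4% ± 3.38. The ZNF genes (62 genes) had 7.32% ± 0.735, with ZNF24 at 7.40% ± 0.596 and ZNF207, above the median of all genes, at 20.1% ± 0.377. The p53 targets (8 genes) had 5.83% ± 1.14, with MDM2, the ligase of p53, listed at 0 and CCNG1 at 5.93% ± 1.29. These 3 lists lay below the random lists. Inside them were mitochondrial ribosomal proteins (19.8%, with MRPL42 at 40.1% and MRPL37 at 9.96%), heat shock and chaperones (33.3%, with HSP90AA1 at 76.8% and HSP90AB1 at 51.8%), cell cycle (20.9%, with CENPF at 45.0% and MCM7 at 33.8%), the stress response list (17.9%, with CALR at 54.5% and HSP90B1 at 19.0%), cap synthesis and decapping (13.3%, with DDX6 at 32.2% and DCP2 at 12.6%), cholesterol synthesis (10.8%, with HMGCR at 9.12% and SQLE at 0.559%) and hypoxia (5.33%, with VEGFA listed at 0 and KDM3A at 9.24%). In all, 9 lists lay outside in HEK293T, 9 in MCF-7 and 8 in mESC. The random lists of MCF-7 and mESC were not matched on expression. In MCF-7 the ribosomal proteins had 60.6% ± 1.94, oxidative phosphorylation 56.1% ± 0.482 and the short-lived mRNAs 12.9% ± 0.863 (n = 2 each) against 35.4% over all genes. In mESC the same lists had 31.0% ± 0.852, 31.0% ± 0.375 and 6.005% ± 0.347 against 12.9%. The mESC count was 5 with 1 isoform per gene.

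**Figure D2:**
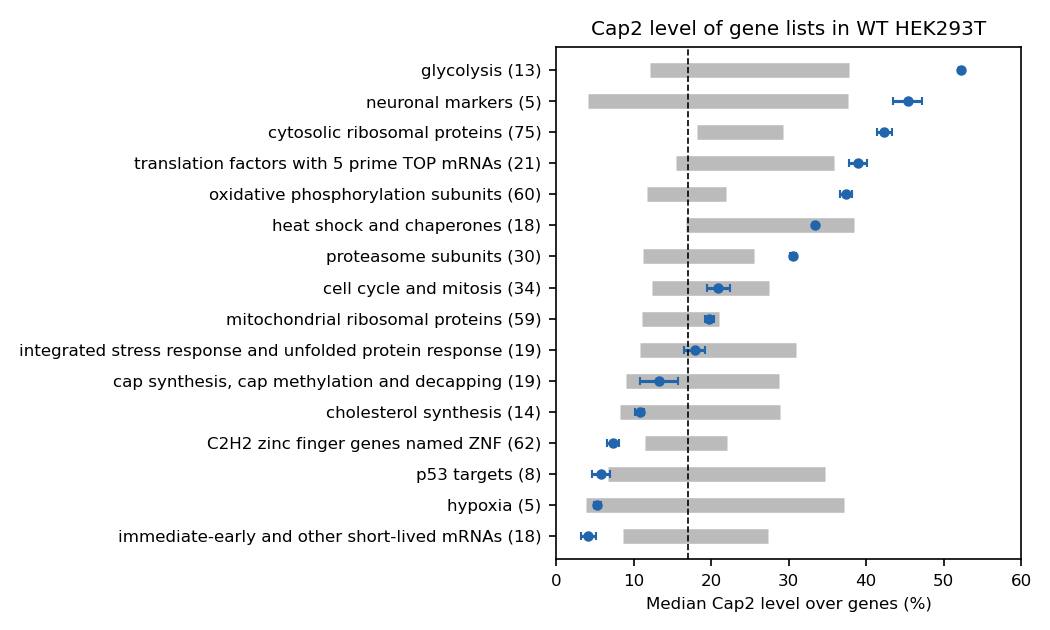
Median Cap2 level of gene lists in WT HEK293T (horizontal axis, percent), with points for the median and lines for the SD over 4 replicates, grey bars for the central 95% of 10000 random lists of equal expression, and a dashed line at 17.1%, the median of all genes. Glycolysis, at 52.2%, and short-lived mRNAs, at 4.16%, lie on opposite sides of their grey bars.

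Longer-lived mRNAs carried more Cap2. From the quartile of isoforms with the shortest half-lives (median 3.07 h) to the quartile with the longest (median 11.3 h), the median Cap2 level went from 11.3% ± 0.227 through 18.5% ± 0.339 and 24.7% ± 0.477 to 31.1% ± 0.852 (SD over 8 pairings of replicates). The gene groups followed this order in part. Short-lived mRNAs had a median half-life of 0.779 h ± 0.0218 (n = 2) and ZNF genes of 1.86 h ± 0.357, while oxidative phosphorylation had 11.2 h ± 1.23, glycolysis 10.7 h ± 0.206 and ribosomal proteins 8.99 h ± 1.00, against 5.81 h ± 0.420 over all genes. The mean rho across 8465 isoforms was 0.278 ± 0.00856, positive in each of the 8 pairings. It was 0.335, 0.282, 0.229 and 0.248 in quartiles of rising expression and 0.274 for MCF-7 levels against HEK293T half-lives. Among isoforms of the same gene the relation was slightly opposite, with a mean rho of -0.0697 over 7293 isoforms, negative in each of the 8 pairings. Cap2 was hardly related to mean ribosome load, with a mean rho of 0.0378 in WT and 0.0308 against the loads of KO cells.

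**Figure D3:**
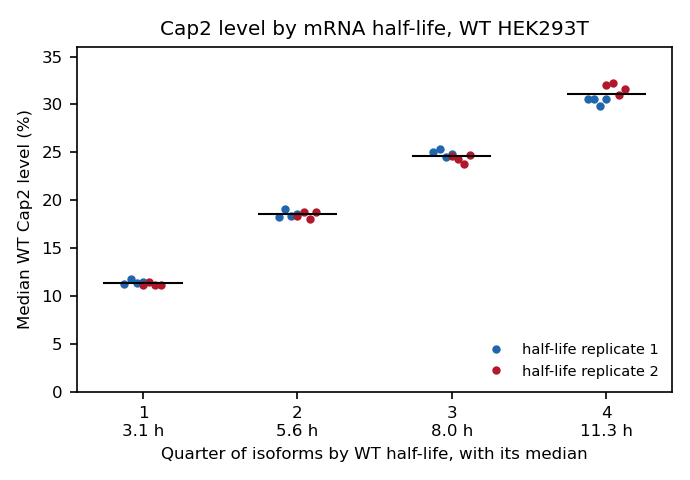
Median Cap2 level (vertical axis, percent) of isoforms in quartiles of half-life (horizontal axis, from shortest to longest) in WT HEK293T. Points are the 8 pairings of half-life and Cap2 replicates and lines their means, which climb from 11.3 to 31.1%.

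Half-lives were compared to see whether mRNA stability differs without CMTR2, and passed the threshold for a single isoform. SLC25A44, a mitochondrial carrier, was the exception. Its isoform at position 156194117 of chromosome 1 went from 1.09 h ± 0.0567 to 2.83 h ± 0.0367 (n = 2 each, log2 change 1.38, limma adjusted p = 0.0488). Of 11426 isoforms tested with limma, 1 rose and 0 fell, with 481 and 679 at an unadjusted p under 0.05. The median log2 change was -0.05. In the simulated data a change of 1 on the log2 scale was recovered in 0 of 200 isoforms and a change of 2 in 142 of 200. The simulation took each isoform's spread, with the shift between replicates, from 2 replicates. It may thus understate what the real comparison could detect. With 2 replicates, isoforms that did not pass are not shown to be unchanged. SLC25A44 did not pass with linear values, centred replicates or a block on replicate number. With 1 replicate left out, whose partner is then assumed to vary like the other group, 18 isoforms rose and 67 fell without WT replicate 1, 84 and 9 without WT replicate 2, 31 and 3 without KO replicate 1, and 31 and 77 without KO replicate 2.

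Mean ribosome load was lower in KO cells across most transcripts. The median over the 10931 isoforms tested was 5.94 ± 0.00601 ribosomes per mRNA in WT and 5.40 ± 0.0371 in KO (SD, n = 2 each). Of these isoforms, 8749 fell, 104 rose and 2078 did not pass (limma), with a median log2 change of -0.13. Among the named falls were the zinc finger factors MAZ (6.87 to 4.83, and 5.51 to 3.75 at another site) and ZNF830 (6.68 to 4.73), the dynein subunit DYNC1LI2 (7.24 to 5.00) and GREB1 (4.11 to 2.93). Rises were RPS2 (3.41 to 4.33), LENG8 (3.04 to 3.85), XAB2 (4.76 to 5.95), MAT2A, which makes S-adenosylmethionine (5.94 to 7.16), and DDX17 (5.49 to 6.56). List medians were not tested. Ribosomal proteins went from a median of 5.02 to 4.44 (76 genes each). For the other lists given here, more genes were measured in KO than in WT. Translation factors went from 7.55 (20 genes) to 6.67 (21), glycolysis from 9.25 (12) to 8.27 (13) and heat shock and chaperones from 8.98 (15) to 8.93 (16). With each replicate centred on its own median, 705 isoforms were lower and 978 higher.

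Whether isoforms with more Cap2 changed more on its loss was tested across isoforms and genes. The change of half-life fell with the WT Cap2 level, with a mean rho of -0.156 ± 0.0172 over 16 pairings (7894 isoforms), and the quartile with the most Cap2 changed by -0.11 on the log2 scale relative to the quartile with the least. Given the mean of the WT and KO half-lives, an adjustment added after the data had been seen, the partial rho was -0.0411. The change of ribosome load had a mean rho of -0.0277 ± 0.0161 (6887 isoforms), and that of RNA-seq expression of -0.0135 ± 0.0186 over 64 pairings (3780 genes), with both signs among the latter. Half-lives of the lists were not tested. Ribosomal proteins stood at 8.99 h in WT and 7.51 h in KO, and oxidative phosphorylation at 11.2 and 9.35 h. ZNF genes stood at 1.86 h over 32 genes in WT and at 3.03 h over 43 genes in KO, so these medians cover different genes. All genes stood at 5.81 h in WT (3740 genes) and 5.68 h in KO (3932 genes).

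RNA-seq set the KO apart from WT for most genes. Of 13473 genes tested with edgeR, 5019 were higher and 4974 lower in KO cells, and 3480 did not pass. At least 2-fold changes numbered 1303 higher and 215 lower. The groups did not overlap for 67.1% of genes, against 2.86% by chance. Changes are relative to TMM scaling. With library size alone all log2 changes shift by a median of 0.150 and 68.5% of the calls are higher in KO, in place of 50.2%. Scaled to the spike-in counts, chosen after the data had been seen, they shift by a median of -0.0438. There 3856 genes were higher and 4571 lower, so 45.8% of the calls were higher. Spike-in counts made up 1.202 to 1.38% of WT and 1.37 to 1.55% of KO libraries.

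Most of the largest rises were of transcripts that WT cells hardly express. ZNF682 and ZNF681, zinc finger genes on chromosome 19, rose from 0.167 to 10.2 and from 0.294 to 12.3 CPM, and ZNF91 from 4.65 to 68.1. The androgen receptor AR rose from 0.208 to 9.80, the antiviral oligoadenylate synthetase OAS3 from 0.695 to 15.5 and FGF13 from 0.577 to 14.1. COL20A1, ERAP2 (which trims antigenic peptides), UNC80 and CLMP also rose, by 4.82, 3.90, 3.77 and 3.69 on the log2 scale. MKX, a homeobox factor, fell from 7.50 to 0.0694 CPM (538 counts in WT, 6 in KO) and PWP2, of ribosome biogenesis, from 8.00 to 0.0908 (8 counts in KO). CPS1, the first enzyme of the urea cycle, fell from 52.6 to 2.39, UNCX from 9.46 to 0.506, SLC13A3 from 14.0 to 2.06, LRATD2 from 61.9 to 11.5, the nuclear receptor ESRRG from 4.75 to 0.506, CLYBL from 7.28 to 1.39 and LEAP2 from 5.06 to 1.09. ENSG00000274276, an identifier without a symbol in the annotation, fell from 5.95 to 0.727, and whether its reads are shared with another locus was not checked. Adjusted p-values of these 20 genes (edgeR, n = 4 each) ran from 1.22e-17 to 1.203e-10. MKX, ESRRG and CLYBL lie in chromosome stretches whose genes were lower together, with neighbour medians of -0.56, -0.46 and -0.51 on the log2 scale.

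Interferon-stimulated and RIG-I signalling genes, which take part in the response to foreign or incompletely methylated RNA, were higher in KO cells. Of 33 members tested, 25 rose, 4 fell and 4 did not pass, the same counts adjusted over the list alone, with a median log2 change of 0.99. OAS3 rose by 4.46, IFIT3, an antiviral partner of IFIT1, by 3.33 (from 0.0861 to 0.898 CPM) and MX1, an antiviral GTPase, by 3.27 (from 0.0690 to 0.743). IRF7, a factor that turns on interferon genes, fell by 4.12. Chosen after their values were seen, STAT2 rose by 1.15 and RIGI stood at -0.12 without passing. The list passed in camera (adjusted p = 7.03e-06), and it alone kept its call with an estimated correlation (adjusted p = 0.0293).

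Genes of protein synthesis were lower. Among 80 ribosomal proteins 77 fell and 1 rose, also adjusted over the list alone, with a median log2 change of -0.39. RPS6 fell by 1.31, RPSA by 0.93, RPS5 by 0.89 and RPS16 by 0.87. RPS6 and RPSA lie in lowered stretches with neighbour medians of -0.32 and -0.37, and after subtraction of each gene's neighbours 79 of 80 ribosomal proteins were still below 0. Among 20 translation factors 17 fell and 0 rose (17 adjusted over the list alone, median -0.36), including EIF3K by 0.86, NPM1, a nucleolar chaperone, by 0.64, the elongation factor EEF1A1 by 0.61 and PABPC1, which binds poly(A) tails, by 0.54. Mitochondrial ribosomal proteins fell in 57 and rose in 2 of 73 (the same adjusted over the list alone, median -0.33), with MRPS6 by 1.02, MRPS25 by 0.98, MRPS12 by 0.93 and MRPL55 by 0.85. MRPS25 and MRPL55 have neighbour medians of -0.33 and -0.61. The adjusted p in camera was 1.08e-17 for ribosomal proteins, 2.05e-07 for translation factors and 5.18e-06 for mitochondrial ribosomal proteins. With an estimated correlation the adjusted p values were 0.204, 0.0953 and 0.190.

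Lists of chaperones, proteasome and metabolic genes passed in camera as lower. Of 22 heat shock and chaperone genes 18 fell and 2 rose (the same adjusted over the list alone, median -0.47). HSPA1B fell by 0.99 and HSPE1 by 0.87, HSPA1A by 1.48, and HSPB1 rose by 0.93. HSPA1A and HSPA1B are near-identical copies, and whether they share reads was not checked. Of 31 proteasome subunits 23 fell and 2 rose (23 and 3 adjusted over the list alone, median -0.21), with PSMD6 lower by -0.58, PSMA4 by -0.55, PSMC4 by -0.54 and PSMD8 by -0.49. PSMD6 and PSMC4 have neighbour medians of -0.33 and -0.36. In cholesterol synthesis 18 of 24 fell and 2 rose (19 and 2 adjusted over the list alone, median -0.30). INSIG1, which holds back sterol synthesis, fell by 0.75, LSS by 0.73 and SQLE by 0.64, and TM7SF2 rose by 0.79. Oxidative phosphorylation had 42 of 75 lower and 6 higher (the same adjusted over the list alone, median -0.12), and glycolysis 11 of 19 lower and 3 higher (the same adjusted over the list alone, median -0.14), and with library size alone the medians of both turn to 0.03 and 0.01. NDUFS4 fell by 0.76, UQCRFS1 by 0.71, ATP5F1C by 0.69 and UQCRC1 by 0.62, the last 2 with neighbour medians of -0.57 and -0.37. GPI fell by 0.83 and the hexokinase HK2 by 0.79, while the enolase ENO2 rose by 1.66 and ALDOC by 0.70. Camera gave adjusted p of 3.37e-10 for chaperones, 0.00209 for proteasome, 0.00181 for cholesterol synthesis, 0.0102 for oxidative phosphorylation and 0.0168 for glycolysis. With an estimated correlation the adjusted p values were 0.0953, 0.180, 0.0953, 0.475 and 0.287. No RNA-seq list was matched on expression. The 3780 genes with a measured Cap2 level had a median log2 change of -0.14, against 0.00495 over all genes tested. The medians of oxidative phosphorylation and glycolysis lay near the former.

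The lists of short-lived mRNAs, of epithelial and renal markers and of mesenchymal and matrix markers passed in camera as higher. Among immediate-early and other short-lived mRNAs, 44 of 59 rose and 5 fell (the same adjusted over the list alone, median 0.55), with MYCN at 3.56, the phosphatase DUSP4 at 2.23, SPRY4 at 2.07 and the cell cycle inhibitor CDKN1A at 2.00 on the log2 scale. Of 13 epithelial and renal markers 10 rose and 2 fell (the same adjusted over the list alone, median 0.79), among them the keratin KRT8 by 3.15, EPCAM by 2.07, the kidney factor PAX2 by 1.86 and CDH1 by 1.16. Of 17 mesenchymal and matrix markers 11 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.56), among them SPARC by 3.39, COL3A1 by 2.32, COL1A1 by 1.66 and ACTA2 by 1.38, while COL4A1, looked up after its value was seen, fell by 1.01 within a lowered stretch of chromosome 13 (median -0.56). Camera gave adjusted p of 1.73e-05, 0.00181 and 0.00437 for these lists, and with an estimated correlation the adjusted p values were 0.204, 0.180 and 0.0953.

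The remaining lists did not pass in camera. Of 28 genes of cap synthesis and decapping 15 fell and 6 rose (the same adjusted over the list alone, median -0.15, and 0.00145 with library size alone), with the exonuclease XRN2 lower by -0.65, NUDT2 by -0.62 (neighbour median -0.49), METTL3 by -0.46 and EDC3 by -0.42. Of 436 ZNF genes 174 rose and 137 fell (173 and 137 adjusted over the list alone, median 0.03, and -0.00966 when scaled to the spike-in counts), with ZNF563 and ZNF229 rising by 4.405 and 4.27. In the cell cycle list 23 of 48 rose and 16 fell (the same adjusted over the list alone, median 0.08). PLK2 rose by 1.45, E2F2 by 0.57 and CDC25B by 0.57, and GMNN fell by 0.65 with a neighbour median of -0.34. In the stress response list 12 of 30 rose and 9 fell (11 and 9 adjusted over the list alone), with a median of -0.00302, a mean of 0.11 and an upward direction in the test. There DDIT3 rose by 1.41, CHAC1 by 1.28, VLDLR by 0.87 within a lowered stretch (neighbour median -0.32) and ASNS by 0.71. Of 25 p53 targets 12 rose and 8 fell (the same adjusted over the list alone, median 0.09), EDA2R by 2.12, GDF15 by 1.93 and TP53INP1 by 1.75. In hypoxia 9 of 19 rose and 6 fell (the same adjusted over the list alone, median 0.09), with ADM, P4HA2 and BNIP3L rising by 1.23, 0.92 and 0.86 and PFKFB3 falling by 0.73 with a neighbour median of -0.57. Of 16 neuronal markers 10 rose and 5 fell (the same adjusted over the list alone, median 0.60), with MAP2, RBFOX3, TUBB3 and CHGB rising by 2.65, 1.96, 1.29 and 1.29. Adjusted p in camera was 0.0894 for cap genes, 0.0980 for ZNF genes, 0.555 for the cell cycle, 0.373 for the stress response, 0.368 for p53 targets, 0.555 for hypoxia and 0.368 for neuronal markers. By fry, which asks whether the members of a list move on balance in 1 direction and compares them with no other genes, all 19 lists passed.

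**Figure D4:**
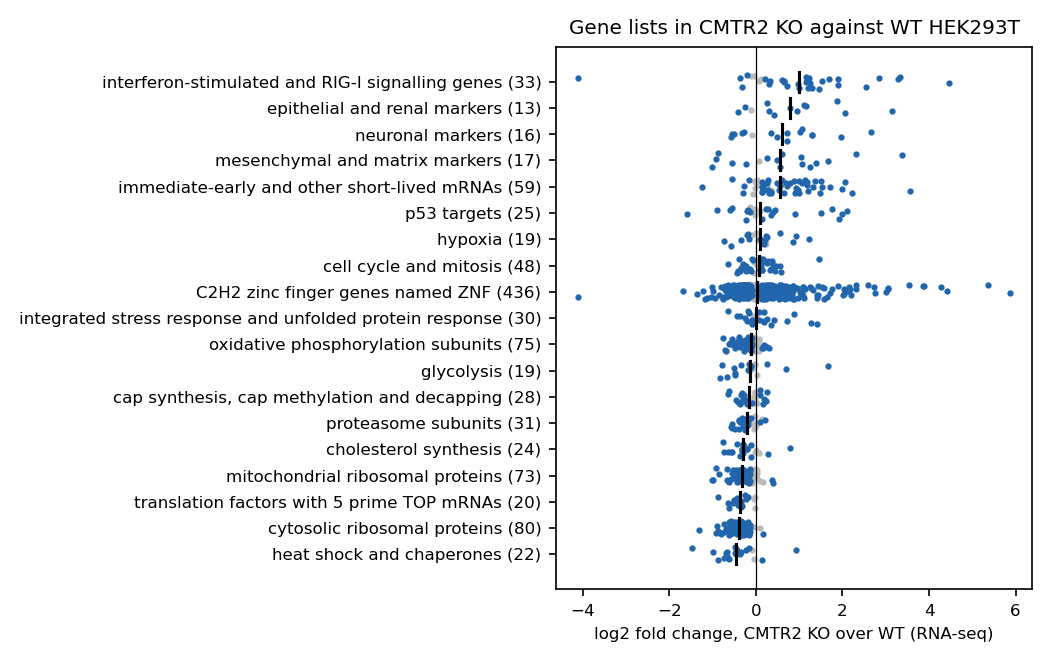
Change of expression in CMTR2 KO against WT HEK293T cells (horizontal axis, log2) for the genes of each list, with points for genes (blue with an adjusted p of 0.05 or less, grey without) and black lines for list medians. Medians run from -0.47 for heat shock and chaperones to 0.99 for interferon-stimulated genes.

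Neighbouring genes shared part of the change. Ordered along the chromosomes, 11 stretches of at least 30 genes had a median change of their neighbourhood beyond 0.3 on the log2 scale, 10 lower and 1 higher in the KO, and none of 100 shuffles of the gene order held any. The end of chromosome 1 from RASSF5 to PGBD2 had a median of -0.53 over 186 genes, of which 142 were lower and 25 higher. Chromosome 10 from ZMYND11 to ZNF239 had -0.59 over 124 genes, and chromosome 13 from DACH1 to CHAMP1 -0.56 over 84. On chromosome 14, from SOCS4 to TMEM121, 220 of 275 genes were higher and 19 lower, with a median of 0.38. The lowered stretches held 1008 genes, 708 lower and 155 higher. The count of stretches was chosen after the result was seen, and DNA was not measured.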

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

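The test of the 4 cell lines against the 6 mouse organs was chosen only after the differences between nucleotides had been seen. Among 206 groups of 4 to 10 values, 11 held a single sample far from the others, which is 5.34% of the groups, and chance alone gives about 1 in 20.

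KO RNA-seq replicate 1 held 29312651 gene counts, against 18988371 to 20045711 in the other 3 KO libraries. In the same library the stress response gene CHAC1 stood at 3.996 log2 CPM (others 4.174 to 4.196) and the keratin KRT8 at 5.10 (others 5.27 to 5.30). CLYBL stood at -0.00359 in KO replicate 2 (others 0.59 to 0.70) and MRPS25 at 6.83 in KO replicate 4 (others 6.86). In WT replicate 2, ENSG00000274276 stood at 2.94 (others 2.42 to 2.47), RPS16 at 8.96 (others 8.88 to 8.89) and PABPC1 at 10.14 (others 10.18). NPM1 stood at 9.77 in WT replicate 1 (others 9.81 to 9.82). In WT replicate 3, MRPS12 stood at 5.74 (others 5.85 to 5.86) and E2F2 at 5.56 (others 5.67 to 5.68). Each of these gene values lies on the same side of all values of the other group as its replicates do, and each gene kept its call when any 1 library was left out.

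Cap2 levels of the nucleotides stood in another order in cell lines than in organs. In organs, mRNAs starting with Am had more Cap2 than those starting with Cm by 20.1 percentage points on average, and in lines they differed by -1.03, a difference between the sets of -21.1 (exact permutation over 210 regroupings, adjusted p = 0.0245). Gm relative to Cm differed between the sets by -23.4 points (adjusted p = 0.0190), Gm relative to Um by -13.0 and Cm relative to Um by 10.4. At the second nucleotide, Cm lay below Um in 4 of 4 lines (-15.4 to -4.44 points) and above it in 6 of 6 organs (1.32 to 36.002 points), a difference between the sets of -26.3 (adjusted p = 0.0190). The sets also differed at the second nucleotide for Am relative to Gm (-18.3), Am relative to Um (-22.4) and Gm relative to Cm (22.2, adjusted p = 0.0429). In all, 8 of 12 pairs passed. Of the lines, mESC is the single mouse source, so line and organ are partly confounded with species, and no explanation was tested. For second Am minus Gm (3.81), second Gm minus Cm (-11.0) and first Cm minus Um (-1.03), mESC lay within the range of the organs. There its sign was opposite to that of the human lines. In the remaining pairs that passed, mESC lay outside the range of the organs, on the side of the human lines.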

How the results depend on the processing

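Scaling to the spike-in counts, limma without a trend, the expression filter on Cap2 results and the partial correlation given mean half-life were chosen after the data had been seen. Of 2834 alternative values, 2675 kept their direction and their side of the threshold or moved within their spread, 55 no longer passed, 14 passed where the reported value did not, 81 moved and 9 reversed. All named RNA-seq genes kept their call in 744 of 744 fits without 1 library, and against a fold of 1.5 (glmTreat) 77 kept it and 16 no longer passed. With that test, 2306 genes passed in place of 9993, 1654 higher and 652 lower, since small changes are not called. With library size alone 3244 genes were lower and 7051 higher, the shift given in the results. Of the 19 gene lists, 1 passed in camera with an estimated correlation and 19 with fry, against 12 as reported.

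The mRNA standards lay a mean of 16.3 points from the line with the ratios of standards 2 and 4 exchanged, and 0.569 with Cap2 taken over all tags of 1 to 3 nt, against 3.09. These distances are sizes without sign. The 0.569 is on a smaller scale, since tags of 1 nt made up 73.4 to 76.8% of the tags of the standards. It therefore does not show a closer match to the line. Of the nucleotide pairs, 0 passed in the 4 lines alone and 0 in the 6 organs alone, with fewer sources, and 8 with partner nucleotides weighted equally. Differences that reversed were, at the first nucleotide, Am minus Cm (-1.03 in lines), Gm minus Cm (1.05 in organs) and Cm minus Um (-3.9993 in organs, -0.650 with equal weights). At the second nucleotide they were Am minus Gm (-9.50 in lines), Am minus Um (3.196 in organs) and Gm minus Cm (1.99 in lines). The last was the nucleotide pair, second position: Cm minus Um (-11.7 in lines, -0.596 with equal weights). The cause was not tested. In mESC, 5 gene lists lay outside the random lists with 1 isoform per gene, against 8.

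For the half-life per isoform, 0 isoforms passed with linear values and 0 with centred replicates, and 5 passed, all of them higher, with half-lives under 16 h. Without 1 library, 34 to 108 passed, of which 18 to 84 were higher and 3 to 77 lower. For Cap2 in KO against WT, 7 to 13 isoforms were higher without 1 library. For mean ribosome load per TSN isoform, CMTR2 KO against WT, 1683 isoforms passed with centred replicates, 978 higher and 705 lower, since centring removes the shared shift. The rank correlation of Cap2 with half-life was 0.353 with 1 isoform per gene, 0.266 for half-lives between 1 and 16 h and 0.265 with the half-lives of the KO cells, against 0.278. That of Cap2 with the change of half-life was -0.228 with 1 isoform per gene and -0.0411 given the mean half-life. The cause was not tested.

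The replicate numbers were not shown to pair the samples. Libraries of the same number correlated across RNA-seq genes with r of -0.316, 0.130, -0.214 and -0.171, and across isoforms with -0.00279 for Cap2, 0.0640 for half-life and 0.0794 for ribosome load. With a block on replicate number, 4939 genes were higher and 4899 lower, 0 half-lives passed, 128 isoforms had a higher and 8909 a lower ribosome load, and 10499 isoforms had less Cap2 in the KO. Coverage minima of 10, 50 and 100 reads and other prior counts were not run, because the tables hold no reads per isoform. Results by start nucleotide and the restriction to isoforms that start with A were not run for want of a genome sequence, and no low values had been filtered, so running without that filter gives nothing new. Unknown depth limits what can be said of isoforms listed at 0, and 2 replicates limit half-lives of single isoforms.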

Other observations

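The count of long chromosome stretches, both counts over other splits of the libraries and the test of ribosome load between quartiles of Cap2 were chosen only after the results had been seen. Some gene groups stood out in the other lines, against random lists not matched on expression. Interferon-stimulated and RIG-I signalling genes, with too few measured genes to be placed in HEK293T, had a median Cap2 level of 67.8% ± 4.80 over 7 genes in MCF-7 (n = 2), above the central 95% of random lists, and 26.1% ± 2.14 over 7 genes in mESC, inside it. Heat shock and chaperone genes lay above the random lists in MCF-7 (58.1% ± 0.659) and mESC (29.2% ± 0.341), and inside them in HEK293T. Mitochondrial ribosomal proteins lay above them in MCF-7 (44.9% ± 0.0304). The p53 targets lay below them in mESC (3.16% ± 0.145) and inside them in MCF-7 (23.5% ± 0.592). Whether the lines differ in these lists was not tested. Across isoforms of WT HEK293T, mean ribosome load had a mean rho of -0.198 ± 0.0183 with half-life (4 pairings, 8130 isoforms).

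In the RNA-seq comparison, median log2 changes by chromosome were -0.33 on chromosome 13 and -0.28 on chromosome 21, and 0.28 on chromosome 14. Of the calls on chromosome 21, 81 were lower and 19 higher. The authors' own table of this comparison, from another test, shares 13302 genes with the edgeR table, and 12811 of them have the same sign, with r = 0.994 across genes and a CMTR2 change of 0.25. The label of the mESC TSS-seq sample names human as the organism, while the other mESC samples name mouse.

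The first pattern is the number of genes that differed between KO and WT RNA-seq. Of the 35 splits of the 8 libraries 1 gave as many, the real one with 9993 (the highest other gave 0). Every other split mixes KO and WT libraries within its groups, which widens their spread, so few calls were to be foreseen there. The splits therefore cannot exclude chance differences between cultures or clones. For the gene lists, 3 of 35 splits gave as many as the real 12 (the highest other also 12), so this count does not exclude chance, but the 16 splits with 3 libraries of a group against 1, which keep part of the difference, gave 9 to 12, and the 18 with 2 of each gave 0 to 5. Copy number of chromosome segments as the main cause was tested on genes changed at least 1.5-fold. The long stretches had medians of -0.59 to -0.30 and of 0.38 on the log2 scale, mostly short of that fold. Genes moved by a stretch alone could thus mostly not enter, and the test cannot decide for smaller changes among the 9993. Among the genes it covers, this cause runs against the 80.2% that still changed at least 1.5-fold after subtraction of their neighbours. This holds for 91.4% of the higher genes but 55.8% of the lower ones, near the bound of 50%, so the weight of copy number among lower genes stays open. For the 3780 genes with a measured Cap2 level, loss of Cap2 from the mRNAs that carry it runs against a mean rho of -0.0135 with that level. The rho says nothing of the other genes tested or of indirect changes. Copy number may account for part of the genes, because 11 long stretches stood against 0 in every shuffle, and because changes of genes 20 places apart correlated with r = 0.0459, above all 1000 shuffles (highest 0.0277) though under the 0.05 set beforehand, but DNA was not measured, and a difference between clones other than CMTR2 remains untested.

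The second pattern is the change of half-life, which was the more negative the more Cap2 an isoform carried in WT. Long half-lives may have been compressed in the KO measurements, since the SD of log2 half-lives was 0.868 in WT and 0.734 in KO. Given the mean half-life, the partial rho was -0.0411 (-0.0786 to -0.000486 over 16 pairings), against -0.156 without. Whether loss of Cap2 shortens half-lives cannot be told apart from this, as the difference between the quartiles with the most and the least Cap2 was -0.0902, -0.0497, -0.0184 and -0.0114 in the 4 quartiles of mean half-life, with both signs among the pairings in the 2 quartiles with the longest half-lives (highest 0.0294 and 0.0280).

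The third pattern is the lower ribosome load in KO cells. For the 6887 isoforms with a measured Cap2 level, loss of Cap2 from the mRNAs that carry it runs against a small difference between quartiles. The mean difference between the quartiles with the most and the least Cap2 was -0.00358 on the log2 scale. A shift shared by all isoforms, as from scaling of the fractions, could account for much of the fall, but 15.4% of isoforms still passed with centred replicates, between the bounds of 5 and 25% set beforehand. A global change of translation cannot be told apart from such scaling, because either would move the isoforms of the KO libraries alike and the steps from fractions to loads are not stated.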
